A study of Homo sapiens with 20 samples.

How the data were processed

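Gene expression was measured by sequencing total RNA from 786-O cells, per the labels with the RNeasy Mini kit for RNA and the TruSeq Stranded Total RNA kit for libraries. Genotype, treatment, time and replicate number of all 20 libraries were taken from the sample labels, and each column of the deposited tables was matched to a library by the genotype, treatment and number in its header. Per the labels the first experiment held PBRM1 wild-type and knockout cells under DMSO or 5 nM bortezomib for 9 h, and the other held both genotypes under DMSO or 10 µM of the ATPase inhibitor BRM014 for 24 h.

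The deposited tables hold each library's read count per gene, as whole numbers that are not normalised, for 12 libraries at 9 h and 8 libraries at 24 h. For the 24 h experiment the authors also gave a DESeq2 log2 fold change per gene and an adjusted p-value for each genotype, and the sign of the log2 column, read from the counts, is DMSO over inhibitor. In the submitters' processing notes STAR, GSNAP and DESeq2 and the builds hg19, hs37d5 and GRCh38 are named without a role or a version. The aligner, the counter and the annotation behind the deposited counts are not given in the sources used here. The 9 h table lists 16767 genes with totals of 92 counts or more over its 12 libraries, so genes with fewer reads had been left out. The 24 h tables list 25553 genes for the knockout and 25701 for the wild type with 23927 in both, each with the counts of all 8 libraries, and their union of 27327 genes was used, with totals of 5 counts or more. The tables also hold 20 log-scale columns, 1 per library, which were not used because the counts were given.

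Depth was 23005121 to 34358221 counts per library at 9 h and 11365110 to 24433007 at 24 h. A count of 0 allows up to 3 counts, which is 0.0873 to 0.130 CPM in a library at 9 h and 0.123 to 0.264 CPM at 24 h. The 10 most abundant genes took 8.95% to 11.3% of the counts at 9 h and 9.15% to 20.9% at 24 h. For a gene with 0 counts in every library of a group, the fold was bounded by setting the group's sum to 3 counts. For 1 to 3 counts the ratio was given with an exact 95% interval of the 2 counts. Floors and intervals cover counting error only, since reads without molecular identifiers are not independent molecules.

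Counts were analysed in R 4.3.3 with edgeR 4.0.16 for each experiment separately. Genes were filtered with filterByExpr, library sizes were scaled by TMM, and a quasi-likelihood model of group means was fitted to all libraries of the experiment without a replicate block. Benjamini-Hochberg adjustment was made within each contrast over 16766 genes at 9 h and 18373 at 24 h, and an adjusted p under 0.05 was the threshold. The contrasts were bortezomib in each genotype, the ATPase inhibitor in each genotype, knockout against wild type under DMSO in each experiment and under bortezomib at 9 h, and the difference of the drug responses between genotypes for each drug. CPM values used the TMM-scaled library sizes. Coordinates of PBRM1 and SMARCA4 came from GENCODE 29 on GRCh38. The pipeline was tested on simulated data with the depths and spread of these libraries and 200 changed genes. At 9 h it recovered 78.1% to 82.8% of genes changed by 0.5 on the log2 scale in the contrasts of groups, and at 24 h 58.7% to 65.2%. For the difference of responses it recovered 71.9% at 9 h and 32.6% at 24 h. The share of false calls in the simulations was 4.67% to 11.6%, above 0.05 in every contrast but the difference of inhibitor responses. Most real contrasts called many more genes than the 200 simulated, so these rates need not hold there.

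Gene lists were written before the data were examined, as were the contrasts, tests, thresholds, the rule for naming genes and most of the alternatives. The 29 lists hold NF-kB targets, proteasome subunits, immunoproteasome, ubiquitin and p97 pathway, heat shock response, integrated stress response, unfolded protein response, NRF2 targets, metallothioneins, autophagy, p53 targets, apoptosis regulators, hypoxia and HIF targets, interferon-stimulated genes, mitosis genes, DNA replication genes, matrix and mesenchymal genes, immediate early and ERK feedback genes, YAP/TEAD targets, cholesterol synthesis, SWI/SNF subunits, ribosomal proteins, mitochondrially encoded genes, nuclear and structural noncoding RNAs, renal identity genes, and markers of leukocytes, endothelium, fibroblasts and nephron segments. Lists with at least 5 measured members, 24 in each contrast, were tested with camera of limma 3.58.1 at a preset correlation of 0.01, which compares a list with the other genes, and the 216 tests were adjusted within each contrast. Members past the threshold were also counted after adjustment over the list alone.

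Named genes were PBRM1, SMARCA4, SMARCA2 and ARID2, the 8 largest rises and the 8 largest falls per contrast among genes with non-overlapping libraries and a mean of at least 1 CPM in the higher group, the 4 members of each list with the smallest p-values and members called against the majority, 9 preset NF-kB targets, the 8 smallest p-values of each difference of responses, the 8 genes with the largest changes in both parts of an overlap, and 4 interferon-stimulated genes at 9 h picked after the 24 h result was seen. The text gives a part of these, and some are not reported here.

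Overlaps of gene sets were tested with Fisher's exact test over the 16477 genes tested in both contrasts, and only contrasts that share no libraries were overlapped or correlated. The knockout effects of the experiments were also compared in a single edgeR model of all 20 libraries and 16761 genes. Medians of log2 fold changes per chromosome used 10216 genes with a mean of at least 5 CPM, with intervals from 2000 bootstrap draws and 1000 shuffles of the gene order (seed 20240601).

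Alternatives replaced a single choice at a time. They were RLE and upper-quartile scaling, no expression filter and a filter of 1 CPM, DESeq2 1.42.0, limma-voom, a fit of the compared groups alone, the replicate number as a block, a 2-fold threshold beside the adjusted p, each library left out in turn, an estimated correlation and fry for the lists, and stricter thresholds for the overlap. Alternatives added after the data were seen were thinning of all libraries to the smallest total, leaving out 2 inhibitor libraries rich in ribosomal RNA, leaving out ribosomal RNA genes, subtracting chromosome medians, the joint model and leaving out libraries for list tests, overlap and correlation.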

Results

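Total RNA was sequenced from 20 libraries of 786-O, a human clear-cell renal carcinoma line, with PBRM1 labelled wild type or knockout. PBRM1 encodes the bromodomain subunit that defines the PBAF form of the SWI/SNF chromatin remodeller. In the first experiment, 12 libraries came from cells given DMSO or 5 nM bortezomib, a proteasome inhibitor, for 9 h, with n = 3 libraries in each of the 4 groups and 23005121 to 34358221 counts per library. In the other experiment, 8 libraries came from cells given DMSO or 10 µM BRM014, an inhibitor of the SMARCA2 and SMARCA4 ATPases of SWI/SNF, for 24 h, with n = 2 libraries per group and 11365110 to 24433007 counts. The labels do not say whether replicates were separate cultures or how many knockout clones were used. Every p-value of a single gene therefore measures the spread between these libraries, which may be technical. P-values of list tests compare a list with the other genes, and those of overlaps count genes. Neither kind measures a spread between libraries, cultures or clones. Expression is in CPM (read counts scaled to a common total per library) as mean ± SD, log2 fold changes and adjusted p-values are from edgeR, and list tests are from camera. A value beside a gene name without a unit is its log2 fold change, or the log2 difference where responses are compared. "Rose", "fell", "higher" and "lower" are used of genes past an adjusted p of 0.05, and the libraries of the groups compared did not overlap for the genes given as largest changes.

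PBRM1 transcript was lower in every knockout library than in every wild-type library of both experiments. At 9 h it was 69.9 ± 0.945 CPM in wild-type DMSO, 67.9 ± 0.828 CPM in wild-type bortezomib, 47.6 ± 1.43 CPM in knockout DMSO and 45.9 ± 1.18 CPM in knockout bortezomib libraries. The 24 h values were 67.5 ± 3.97 CPM in wild-type DMSO, 72.0 ± 3.76 CPM in wild-type inhibitor, 47.0 ± 2.50 CPM in knockout DMSO and 50.3 ± 1.47 CPM in knockout inhibitor libraries. The knockout difference under DMSO was -0.56 on the log2 scale at 9 h (SE 0.0331, adjusted p = 1.83e-13) and -0.52 at 24 h (SE 0.0693, adjusted p = 2.67e-05). The gene spans 52545352 to 52685917 on the minus strand of chromosome 3 (GRCh38, GENCODE 29). The labels do not say what was edited, and a transcript level does not measure the protein.

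**Figure D1:**
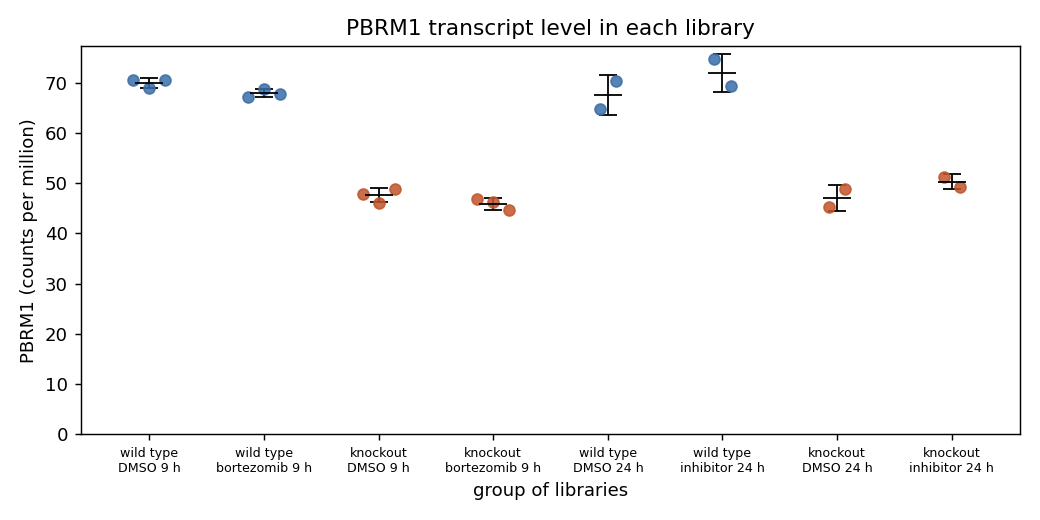
PBRM1 CPM on the vertical axis for each of the 8 groups on the horizontal axis, with a point per library and the mean ± SD, wild type in blue and knockout in orange. Knockout libraries lay at 44.6 to 51.3 CPM and wild-type libraries at 64.7 to 74.6 CPM.

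SMARCA4, which encodes an ATPase of SWI/SNF and lies at 10960825 to 11079426 on the plus strand of chromosome 19, did not pass the threshold between knockout and wild type under DMSO at 9 h (-0.01, adjusted p = 0.765) or at 24 h (-0.00361, adjusted p = 0.981). Neither did the other ATPase gene, SMARCA2, at 9 h (-0.06, adjusted p = 0.114, but past it at -0.09 without wild-type DMSO library 2) or 24 h (-0.08, adjusted p = 0.366), nor ARID2, another PBAF subunit (0.02, adjusted p = 0.704 and -0.02, adjusted p = 0.867). Bortezomib raised SMARCA2 in wild-type cells (0.15) and in knockout cells (0.35). Under the ATPase inhibitor SMARCA2 fell from 93.2 ± 0.107 to 53.8 ± 0.0651 CPM in wild-type cells (log2 fold change -0.79, SE 0.0612, adjusted p = 4.44e-08) and from 88.5 ± 0.0890 to 65.1 ± 1.48 CPM in knockout cells (log2 fold change -0.44, SE 0.0601, adjusted p = 2.63e-05). The difference between these falls did not pass the threshold (0.35, adjusted p = 0.0606), except with upper-quartile factors (0.37) or without knockout inhibitor library 1 (0.37). Inhibitor-treated libraries had higher ARID2 in wild-type (0.36) and knockout cells (0.25), where it did not pass without knockout inhibitor library 1 (0.17) or knockout DMSO library 1 (0.21). Of 25 measured SWI/SNF subunits at 9 h, bortezomib in wild-type cells gave 1 rise and 5 falls, the list passing at adjusted p = 0.0368 but at adjusted p = 0.0707 with an estimated correlation.

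The comparison of bortezomib with DMSO in wild-type cells asked what proteasome inhibition changes while PBRM1 is present. HMOX1, the haem oxygenase gene that NRF2 drives, rose from 62.6 ± 3.02 to 214 ± 11.1 CPM (n = 3 each; log2 fold change 1.77, SE 0.0351, adjusted p = 6.69e-23). PSMC4, an ATPase subunit of the proteasome itself, rose from 116 ± 2.32 to 186 ± 2.90 CPM (log2 fold change 0.69, SE 0.0265, adjusted p = 1.07e-16). BIRC3, an apoptosis inhibitor that NF-kB induces, fell from 197 ± 9.24 to 127 ± 0.385 CPM (log2 fold change -0.64, SE 0.0335, adjusted p = 5.13e-14). TNF fell from 18.7 ± 0.734 to 9.54 ± 0.946 CPM (log2 fold change -0.96, SE 0.0738, adjusted p = 9.08e-11). In total 3902 of 16766 tested genes changed, 2046 upward and 1856 downward, and 98 of them changed at least 2-fold (69 upward and 29 downward).

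The largest rises included HTRA3 (2.37), SH3TC2 (2.23), TDO2 (2.01) and HSPA6 (1.62), and the largest falls included PIGZ (-1.20), NOG (-0.97) and the transcription factors SOX9 (-0.95) and HMGA2 (-0.84). Among 33 proteasome subunits, 33 of 33 rose and 0 fell, the same numbers adjusted over the list alone (median log2 fold change 0.37, adjusted p = 3.29e-52). Of the 28 heat shock genes, 24 of 28 rose and 0 fell, or 25 and 0 adjusted over the list alone (median log2 fold change 0.24, adjusted p = 5.75e-30). HSPA1A was at 1.38, HSPA1B at 1.37 and DNAJB1 at 0.61. Reads of HSPA1A and HSPA1B, which are nearly identical, may not be told apart. Among 29 integrated stress response genes, 24 of 29 rose and 0 fell, or 25 and 0 adjusted over the list alone (median log2 fold change 0.37, adjusted p = 5.00e-25), including CHAC1 (1.27) and the cystine transporter gene SLC7A11 (0.97). Of 42 measured NF-kB targets, 33 fell and 1 rose, the same numbers adjusted over the list alone (median log2 fold change -0.32, adjusted p = 6.05e-22). They included IL8, now called CXCL8 (-0.53), TNFAIP3 (-0.50), IL6 (-0.73) and NFKBIA (-0.34), and the exception was MMP9 (0.57), which did not pass without wild-type DMSO library 1 (0.51) or 2 (0.47) or wild-type bortezomib library 3 (0.41).

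The ubiquitin and p97 list also rose in wild-type cells, where 15 of 19 rose and 1 fell, or 17 and 1 adjusted over the list alone (median log2 fold change 0.32, adjusted p = 5.80e-18). VCP was at 0.46. For NRF2 targets, 20 of 22 rose and 0 fell, the same numbers adjusted over the list alone (median log2 fold change 0.34, adjusted p = 6.81e-25). GCLM was at 0.68. Of 21 unfolded protein response genes, 18 rose and 0 fell, the same numbers adjusted over the list alone (median log2 fold change 0.17, adjusted p = 8.78e-15). HERPUD1 was at 0.78. Autophagy genes gave a like result, as 7 of 13 rose and 0 fell, or 10 and 0 adjusted over the list alone (median log2 fold change 0.19, adjusted p = 6.12e-07), led by GABARAPL1 (0.89) and SQSTM1 (0.79). In the cholesterol synthesis list, 10 of 23 rose and 0 fell, the same numbers adjusted over the list alone (median log2 fold change 0.10, adjusted p = 9.59e-06). Of immediate early and ERK feedback genes, 9 of 18 fell and 1 rose, the same numbers adjusted over the list alone (median log2 fold change -0.25, adjusted p = 6.70e-06). SPRY2 was at -0.78 and JUNB at -0.45. For 28 mitosis genes, 11 fell and 0 rose, or 15 and 1 adjusted over the list alone (median log2 fold change -0.07, adjusted p = 4.45e-05), and for 26 DNA replication genes, 9 of 26 fell and 1 rose, or 11 and 1 adjusted over the list alone (median log2 fold change -0.07, adjusted p = 0.00120, adjusted p = 0.0873 with an estimated correlation). Of 48 ribosomal proteins, 25 rose and 0 fell, or 32 and 0 adjusted over the list alone (median log2 fold change 0.07, adjusted p = 6.10e-10, adjusted p = 0.236 with an estimated correlation). Of 9 renal identity genes 4 fell (adjusted p = 0.0121 for the list), among them LHX1 (-0.32). Interferon-stimulated genes (6 rose and 4 fell of 28, adjusted p = 0.511), p53 targets (adjusted p = 0.487) and hypoxia and HIF targets (adjusted p = 0.0669) did not pass as lists. Of 24 lists tested, 18 passed, and 12 with an estimated correlation.

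In knockout cells bortezomib was compared with DMSO to ask the same without PBRM1, and the difference from wild type was tested separately. CHAC1, a glutathione-degrading enzyme gene of the integrated stress response, rose from 7.26 ± 0.199 to 75.9 ± 0.776 CPM (log2 fold change 3.38, SE 0.0639, adjusted p = 1.07e-24). HMOX1 rose from 46.9 ± 0.556 to 405 ± 7.27 CPM (log2 fold change 3.11, SE 0.0359, adjusted p = 6.91e-29). CCL2, a monocyte chemokine gene, fell from 147 ± 1.95 to 27.2 ± 1.04 CPM (log2 fold change -2.43, SE 0.0379, adjusted p = 2.08e-26), TNF fell from 27.9 ± 1.13 to 2.16 ± 0.0960 CPM, and NFKBIA, which encodes the inhibitor of NF-kB, fell from 132 ± 1.24 to 45.8 ± 1.36 CPM. CCND1, the cyclin D1 gene, fell from 252 ± 2.83 to 72.4 ± 2.82 CPM (log2 fold change -1.80, SE 0.0286, adjusted p = 2.88e-26). Altogether 8153 of 16766 genes changed, 3983 upward and 4170 downward, and 715 changed at least 2-fold (291 upward and 424 downward).

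Other large rises were HSPA6 (3.98), CTH (3.74), INHBE (3.31) and PGF (3.35), and other large falls were CSF2 (-5.60), EDN2 (-3.02), ATOH8 (-2.72) and PTX3 (-2.47). Of 42 NF-kB targets, 38 fell and 2 rose, or 39 and 2 adjusted over the list alone (median log2 fold change -0.99, adjusted p = 2.93e-24). BIRC3 was at -2.13, TNFAIP3 at -1.61 and RELB at -0.84, against MMP9 (1.03) and GADD45B (0.44). For the integrated stress response, 28 of 29 rose and 1 fell, the same numbers adjusted over the list alone (median log2 fold change 1.27, adjusted p = 9.15e-29). SESN2 was at 2.90 and DDIT4 at 2.59, against ATF5 (-1.01). For heat shock genes, 26 of 28 rose and 0 fell, or 27 and 0 adjusted over the list alone (median log2 fold change 0.75, adjusted p = 1.33e-27). HSPA1A was at 3.10 and BAG3 at 1.72. Of 33 proteasome subunits, 33 rose and 0 fell, the same numbers adjusted over the list alone (median log2 fold change 0.46, adjusted p = 1.22e-26), PSMC4 rising by 1.02 and PSMD14 by 0.81. In the ubiquitin and p97 list, 15 of 19 rose and 2 fell, the same numbers adjusted over the list alone (median log2 fold change 0.49, adjusted p = 6.27e-09). ZFAND2A was at 2.43. Mitosis genes moved down, as 23 of 28 fell and 2 rose, the same numbers adjusted over the list alone (median log2 fold change -0.29, adjusted p = 6.37e-11). CCNF was at -0.79. DNA replication genes did so too, as 23 of 26 fell and 1 rose, the same numbers adjusted over the list alone (median log2 fold change -0.40, adjusted p = 4.55e-11). UHRF1 was at -0.73. Apoptosis regulators were not called as a list (adjusted p = 0.0729), although BCL2L1 (-0.997) and BCL2 (-1.29) fell. Of 13 mitochondrially encoded genes, 12 rose and 0 fell, or 13 and 0 adjusted over the list alone (median log2 fold change 0.40, adjusted p = 0.00555, adjusted p = 0.448 with an estimated correlation). Among 31 matrix and mesenchymal genes, 15 of 31 rose and 5 fell, or 15 and 6 adjusted over the list alone (median log2 fold change 0.17, adjusted p = 0.0126, adjusted p = 0.174 with an estimated correlation). For the 5 nuclear and structural noncoding RNAs, 4 of 5 rose and 0 fell, the same numbers adjusted over the list alone (median log2 fold change 0.62, adjusted p = 0.0129, adjusted p = 0.164 with an estimated correlation). MALAT1 was at 0.90 and NEAT1 at 0.98. In total 15 of 24 lists passed, and 12 with an estimated correlation.

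**Figure D2:**
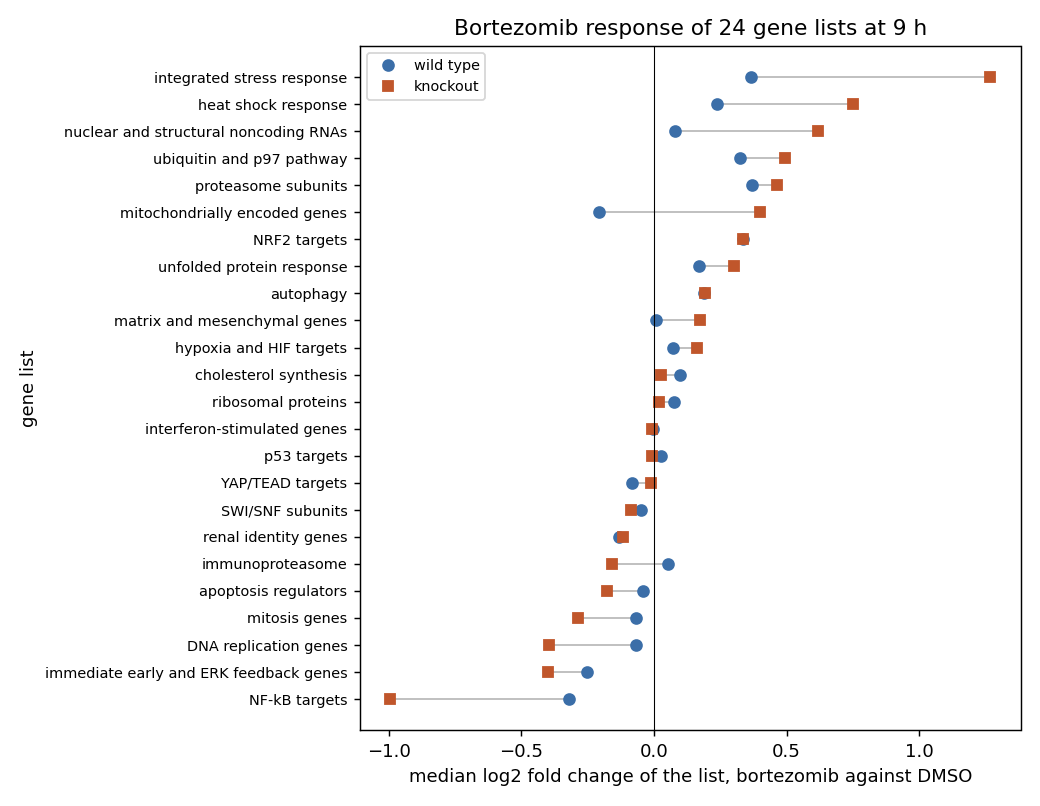
Median log2 fold change under 9 h of bortezomib on the horizontal axis for each gene list on the vertical axis, circles for wild-type and squares for knockout cells (3 libraries per group). The NF-kB median was -0.32 in wild type and -0.99 in knockout, and that of the proteasome subunits was 0.37 and 0.46.

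The difference between these responses was tested directly, asking whether PBRM1 loss alters the bortezomib response. DDIT4, a stress-induced inhibitor of mTORC1, rose more in knockout cells (log2 difference 1.95, SE 0.0473, adjusted p = 1.06e-20), as did SESN2 (log2 difference 2.17, SE 0.0682, adjusted p = 1.11e-18) and STC2 (log2 difference 1.71, SE 0.0430, adjusted p = 1.43e-20). CCL2 fell more (log2 difference -1.96, SE 0.0544, adjusted p = 7.82e-20), as did EDN2 (-2.28), BIRC3 (log2 difference -1.49, SE 0.0489, adjusted p = 2.57e-18) and CCND1 (log2 difference -1.38, SE 0.0382, adjusted p = 7.82e-20). The PBRM1 transcript itself did not differ in response (-0.01, adjusted p = 0.929). Responses differed for 4327 of 16766 genes, with 2097 more positive and 2230 more negative in the knockout and 275 at least 2-fold (110 more positive and 165 more negative).

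Of 42 NF-kB targets, 33 were lower and 1 was higher, or 34 and 1 adjusted over the list alone (median log2 difference -0.57, adjusted p = 6.11e-28). NFKBIA was at -1.18, TNFAIP3 at -1.11 and RELB at -0.61. CXCL1 did not pass (-0.51, adjusted p = 0.113). Of integrated stress response genes, 27 of 29 were higher and 1 was lower, the same numbers adjusted over the list alone (median log2 difference 0.84, adjusted p = 2.29e-42). ASNS was at 1.304. Heat shock genes had larger rises in the knockout, as 26 of 28 were higher and 0 were lower, the same numbers adjusted over the list alone (median log2 difference 0.45, adjusted p = 1.48e-34). HSPA1A was at 1.72 and DNAJB1 at 1.12. Proteasome subunits differed by less, as 15 of 33 were higher and 0 were lower, or 16 and 0 adjusted over the list alone (median log2 difference 0.08, adjusted p = 7.54e-07). PSMC4 was at 0.33. For the ubiquitin and p97 list, 9 of 19 were higher and 1 was lower, or 9 and 2 adjusted over the list alone (median log2 difference 0.10, adjusted p = 0.00247). NRF2 targets did not pass as a list, as 4 of 22 were higher and 3 were lower, the same numbers adjusted over the list alone (median log2 difference -0.00197, mean 0.04, test upward, not all of 1 sign, adjusted p = 0.231), although HMOX1 (1.34) and SLC7A11 (0.87) rose more. Of DNA replication genes, 19 of 26 were lower and 1 was higher, or 21 and 1 adjusted over the list alone (median log2 difference -0.33, adjusted p = 4.54e-13). PCNA was at -0.48. Of mitosis genes, 19 of 28 were lower and 1 was higher, or 21 and 1 adjusted over the list alone (median log2 difference -0.21, adjusted p = 3.07e-11). KIF20A was at -0.62. For the unfolded protein response, 12 of 21 were higher and 0 were lower, or 14 and 1 adjusted over the list alone (median log2 difference 0.13, adjusted p = 1.90e-06, adjusted p = 0.0553 with an estimated correlation). HERPUD1 was at 0.84. For mitochondrially encoded genes, 11 of 13 were higher and 0 were lower, or 12 and 0 adjusted over the list alone (median log2 difference 0.60, adjusted p = 1.24e-05, adjusted p = 0.261 with an estimated correlation).

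The bortezomib log2 fold changes of wild-type and knockout cells, which share no libraries, were compared across all 16766 genes. They correlated at Pearson's r = 0.502 and Spearman's rho = 0.511. Their spread was 1.80 times as wide in the knockout after the median squared SE was subtracted from the variance in each genotype. Noise of genes with larger SEs stays in this ratio. It was 1.99 over genes with at least 1 CPM in 3 libraries and 2.09 over genes past the threshold in either contrast. Genes are not independent replicates, so no p-value is attached to this correlation.

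**Figure D3:**
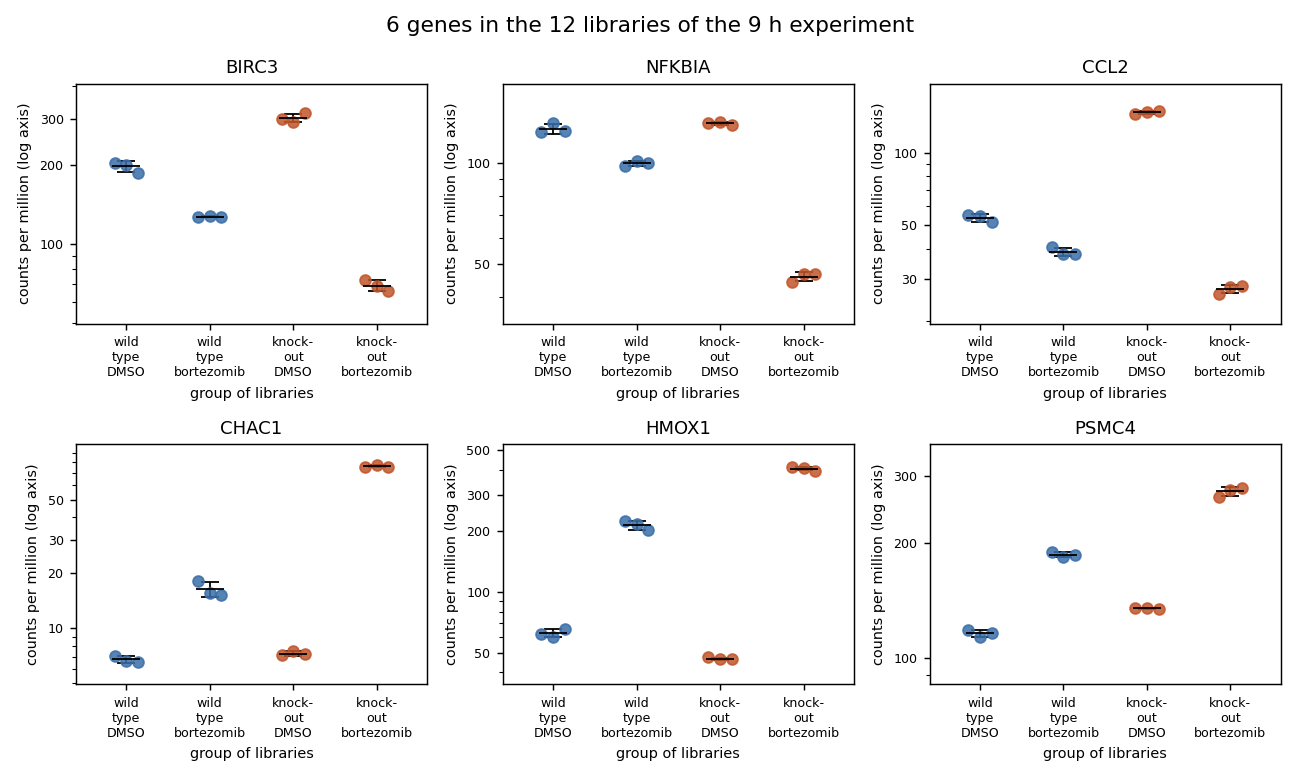
CPM on a log axis for selected genes in the 4 groups at 9 h, a point per library with the mean ± SD, wild type in blue and knockout in orange. CCL2 in the knockout fell from 147 ± 1.95 to 27.2 ± 1.04 CPM, and CHAC1 rose from 7.26 ± 0.199 to 75.9 ± 0.776 CPM.

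Knockout and wild-type DMSO libraries at 9 h were compared to ask what PBRM1 loss changes without a drug. Several genes expressed in wild type had no counts in the 3 knockout libraries. DSP, which encodes the desmosome protein desmoplakin, was at 17.4 ± 0.716 CPM in wild type and at least 595-fold lower in the knockout. CHRDL1, a secreted BMP antagonist gene, was at 11.1 ± 0.820 CPM and at least 378-fold lower, and the floor behind these bounds is 3 counts over the group. In the other direction CLDN2, a tight-junction claudin gene, was at 86.9 ± 1.47 against 7.24 ± 0.464 CPM (log2 fold change 3.59, SE 0.0655, adjusted p = 1.40e-24). COL6A3, a collagen VI chain gene, was lower (13.4 ± 1.20 against 62.3 ± 1.29 CPM, log2 fold change -2.22, SE 0.0543, adjusted p = 8.31e-22). Altogether 7019 of 16766 genes differed, 3752 higher and 3267 lower, and 689 by at least 2-fold (245 higher and 444 lower).

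STK33 (at least 84.3-fold), CDH11 (at least 63.1-fold) and MSX2 (at least 56.3-fold) were also lower against a knockout group at 0. C4BPB (4.14), SPINT1 (3.42), IRF8 (4.54) and UGT2A3 (3.45) were higher. NF-kB targets went both ways. Of 42, 24 of 42 were higher and 11 were lower, or 24 and 12 adjusted over the list alone (median log2 fold change 0.21, adjusted p = 0.00626, adjusted p = 0.183 with an estimated correlation), with CCL2 (1.45), BIRC3 (0.62) and TNFAIP3 (0.36) higher and CXCL1 (-1.22), VCAM1 (-0.84) and IL6 (-0.82) lower. Of 31 matrix and mesenchymal genes, 19 were lower and 5 were higher, the same numbers adjusted over the list alone (median log2 fold change -0.29, adjusted p = 2.55e-06, adjusted p = 0.123 with an estimated correlation). FN1 was higher (0.63). The matrix median was the same with its member at 0 set to the bound. Of 20 YAP/TEAD targets, 13 were lower and 1 was higher, the same numbers adjusted over the list alone (median log2 fold change -0.14, adjusted p = 7.33e-06, adjusted p = 0.123 with an estimated correlation). CCDC80 was at -2.49. Of 23 p53 targets, 9 were lower and 4 were higher, or 10 and 4 adjusted over the list alone (median log2 fold change -0.13, adjusted p = 0.0197, adjusted p = 0.183 with an estimated correlation). CDKN1A was at -1.38 and TP53INP1 at -1.52. All 5 immunoproteasome genes were higher, PSMB8 by 0.55 (adjusted p = 0.000857 for the list, adjusted p = 0.123 with an estimated correlation). Mitochondrially encoded genes were lower, as 13 of 13 were lower and 0 were higher, the same numbers adjusted over the list alone (median log2 fold change -0.93, adjusted p = 1.36e-07, adjusted p = 0.189 with an estimated correlation). MT-CYB was at -0.99.

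Proteasome subunits at 9 h under DMSO were mostly higher in the knockout, as 19 of 33 were higher and 3 were lower, or 20 and 4 adjusted over the list alone (median log2 fold change 0.09, adjusted p = 0.00327, adjusted p = 0.183 with an estimated correlation). For the unfolded protein response, 14 of 21 were higher and 0 were lower, the same numbers adjusted over the list alone (median log2 fold change 0.138, adjusted p = 2.72e-06, adjusted p = 0.123 with an estimated correlation). SDF2L1 was at 0.52. For the integrated stress response, 16 of 29 were lower and 6 were higher, or 17 and 6 adjusted over the list alone (median log2 fold change -0.15, adjusted p = 0.0207, adjusted p = 0.189 with an estimated correlation), with STC2 (-0.52) lower and SLC7A11 (1.004) higher. Interferon-stimulated genes did not pass as a list, since 11 of 28 were lower and 10 were higher, or 12 and 11 adjusted over the list alone (median log2 fold change -0.03, adjusted p = 0.584). SAMD9L was at -2.06. In this comparison 14 of 24 lists passed, and 0 with an estimated correlation.

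Under bortezomib the knockout was compared with wild type at 9 h to describe the states reached in the presence of the drug. LCP1, which encodes the actin-bundling protein L-plastin, was at 1157 ± 22.02 against 124 ± 3.59 CPM (log2 fold change 3.22, SE 0.0280, adjusted p = 5.26e-32). IL8 was lower in the knockout (31.0 ± 2.92 against 90.9 ± 3.65 CPM, log2 fold change -1.54, SE 0.0452, adjusted p = 2.24e-20), and NFKBIA was at 45.8 ± 1.36 against 100.05 ± 1.71 CPM (log2 fold change -1.13, SE 0.0332, adjusted p = 2.47e-20). CHRDL1, at 11.9 ± 0.129 CPM in wild type, was at least 288-fold lower against 0 counts in the knockout, and CLEC2B was at least 92.2-fold lower. Altogether 8129 of 16766 genes differed, 4095 higher and 4034 lower, and 874 by at least 2-fold (263 higher and 611 lower).

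C4BPB (4.28), UGT2A3 (3.40), CPA6 (3.22) and INHBE (2.88) were among the genes highest in the treated knockout. Of NF-kB targets, 29 of 42 were lower and 6 were higher, or 30 and 6 adjusted over the list alone (median log2 fold change -0.43, adjusted p = 1.28e-09). CXCL1 was at -1.73, TNFAIP2 at -1.36 and CCL2 at -0.51. For heat shock genes, 25 of 28 were higher and 1 was lower, or 26 and 1 adjusted over the list alone (median log2 fold change 0.59, adjusted p = 3.61e-21). HSPA1A was at 2.57. For the integrated stress response, 24 of 29 were higher and 3 were lower, the same numbers adjusted over the list alone (median log2 fold change 0.72, adjusted p = 2.65e-17). SLC7A11 was at 1.87 and ASNS at 1.34, against GDF15 (-1.96). Proteasome subunits were higher, as 27 of 33 were higher and 1 was lower, the same numbers adjusted over the list alone (median log2 fold change 0.18, adjusted p = 2.45e-09). PSMC4 was at 0.55. For the unfolded protein response, 18 of 21 were higher and 1 was lower, or 19 and 1 adjusted over the list alone (median log2 fold change 0.32, adjusted p = 8.09e-11). HERPUD1 was at 1.31. Mitosis genes were lower, as 22 of 28 were lower and 2 were higher, the same numbers adjusted over the list alone (median log2 fold change -0.19, adjusted p = 2.61e-07), and CCND1 was lower by a log2 fold change of -1.88. Of p53 targets, 16 of 23 were lower and 3 were higher, the same numbers adjusted over the list alone (median log2 fold change -0.38, adjusted p = 0.0131, adjusted p = 0.179 with an estimated correlation). CDKN1A was at -0.82. Ribosomal protein genes were lower, as 33 of 48 were lower and 2 were higher, the same numbers adjusted over the list alone (median log2 fold change -0.10, adjusted p = 5.18e-07, adjusted p = 0.330 with an estimated correlation). Of 24 lists 12 passed, and 6 with an estimated correlation.

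The 24 h comparison of the ATPase inhibitor with DMSO in wild-type cells asked which genes need SWI/SNF activity. CLDN2 fell from 84.0 ± 5.70 to 0.267 ± 0.0244 CPM (n = 2 each; log2 fold change -8.25, SE 0.161, adjusted p = 8.50e-15). ANGPTL4, a secreted lipoprotein lipase inhibitor gene, rose from 6.12 ± 0.306 to 122 ± 2.63 CPM (log2 fold change 4.31, SE 0.0828, adjusted p = 8.50e-15). OAS3, an antiviral 2-5A synthetase gene, fell from 344 ± 9.27 to 103 ± 0.770 CPM (log2 fold change -1.74, SE 0.0696, adjusted p = 2.18e-11), and FN1, the fibronectin gene, fell from 5913 ± 32.3 to 1883 ± 17.03 CPM (log2 fold change -1.65, SE 0.0725, adjusted p = 6.05e-11). PDLIM4 was at least 28.8-fold lower and NTRK3 at least 25.9-fold lower against 0 counts in the treated cells. Of 18373 tested genes 6902 changed, 3328 upward and 3574 downward, and 1736 at least 2-fold (693 upward and 1043 downward). Wild-type inhibitor library 2 and knockout inhibitor library 1 had the lowest depth, 12779017 and 11365110 counts, and 4.18% and 5.98% of their counts in mitochondrial ribosomal RNA.

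TRPV2 (5.80), STEAP1B (4.36) and SULT2B1 (4.27) were among the largest rises under the inhibitor in wild-type cells. FCAMR kept 1 count in the treated libraries, a DMSO over inhibitor ratio of 314 with a counting interval of 56.1 to 12425. Of 31 interferon-stimulated genes, 28 fell and 1 rose, or 29 and 1 adjusted over the list alone (median log2 fold change -1.30, adjusted p = 3.05e-16, adjusted p = 0.0885 with an estimated correlation). RSAD2 was at -2.94, IFI44L at -4.02 and BST2 at -1.36, against IFI35 (0.24). IFI35 did not pass without wild-type inhibitor library 1 (0.22) or 2 (0.25) or wild-type DMSO library 1 (0.26) or 2 (0.21). Of 24 cholesterol synthesis genes, 16 fell and 1 rose, the same numbers adjusted over the list alone (median log2 fold change -0.48, adjusted p = 2.34e-06, adjusted p = 0.0885 with an estimated correlation). INSIG1 was at -2.19. Of 30 matrix and mesenchymal genes, 19 fell and 3 rose, or 19 and 4 adjusted over the list alone (median log2 fold change -0.45, adjusted p = 1.84e-06, adjusted p = 0.0885 with an estimated correlation). FSTL1 was at -1.46. DNA replication genes fell, as 20 of 26 fell and 0 rose, the same numbers adjusted over the list alone (median log2 fold change -0.40, adjusted p = 6.20e-08, adjusted p = 0.147 with an estimated correlation). UHRF1 was at -1.34. For the unfolded protein response, 15 of 21 fell and 1 rose, or 16 and 1 adjusted over the list alone (median log2 fold change -0.51, adjusted p = 9.61e-07, adjusted p = 0.147 with an estimated correlation). XBP1 was at -0.81. Hypoxia and HIF targets fell on balance, as 13 of 25 fell and 3 rose, the same numbers adjusted over the list alone (median log2 fold change -0.26, adjusted p = 0.00168, adjusted p = 0.248 with an estimated correlation). IGFBP3 was at -2.01. NF-kB targets split, since 16 of 46 fell and 14 rose, or 16 and 15 adjusted over the list alone (median log2 fold change -0.03, adjusted p = 0.735). IL8 was at -1.27 and IL6 at -2.03, against CCL2 at 1.75, RELB at 0.96 and BIRC3 at 0.82. Heat shock genes fell more often, as 19 of 28 fell and 3 rose, or 19 and 4 adjusted over the list alone (median log2 fold change -0.27, adjusted p = 0.00210, adjusted p = 0.298 with an estimated correlation). SERPINH1 was at -2.28. Renal identity genes fell, as 7 of 9 fell and 0 rose, the same numbers adjusted over the list alone (median log2 fold change -0.64, adjusted p = 0.000789, adjusted p = 0.298 with an estimated correlation). CDH16 was at -2.85 and PAX8 at -0.64. HMOX1 rose by a log2 fold change of 2.49, and AXL, a YAP/TEAD target, fell (-2.01). Of 24 lists 14 passed, and 0 with an estimated correlation.

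Knockout cells given the ATPase inhibitor were compared with knockout DMSO cells to ask what the remaining SWI/SNF activity maintains. CLDN2 fell from 159.7 ± 5.20 to 0.448 ± 0.172 CPM (log2 fold change -8.62, SE 0.1399, adjusted p = 6.70e-16), and IGFBP3, which encodes a binding protein for insulin-like growth factors, fell from 1195 ± 28.4 to 75.2 ± 0.0220 CPM (log2 fold change -3.99, SE 0.0659, adjusted p = 6.70e-16). ANGPTL4 rose from 1.01 ± 0.0626 to 67.5 ± 4.05 CPM. CSF2 was at least 54.7-fold lower and IRF8 at least 45.6-fold lower against 0 counts under the inhibitor. Of 18373 genes 6417 changed, 3083 upward and 3334 downward, and 1570 at least 2-fold (653 upward and 917 downward).

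SYT11 (4.03) and SULT2B1 (4.201) were among the largest rises in the knockout. Of interferon-stimulated genes, 18 of 31 fell and 5 rose, or 19 and 6 adjusted over the list alone (median log2 fold change -0.61, adjusted p = 0.000197, adjusted p = 0.245 with an estimated correlation). OASL was at -3.69 and IFIT3 at -0.99, against IFI35 (0.85) and IFIH1 (0.68). For cholesterol synthesis, 17 of 24 fell and 1 rose, or 19 and 2 adjusted over the list alone (median log2 fold change -0.43, adjusted p = 1.89e-07, adjusted p = 0.0883 with an estimated correlation). INSIG1 was at -2.36 and HMGCS1 at -1.17. DNA replication genes fell here too, as 18 of 26 fell and 0 rose, or 19 and 0 adjusted over the list alone (median log2 fold change -0.35, adjusted p = 1.89e-07, adjusted p = 0.196 with an estimated correlation). UHRF1 was at -1.19. Of matrix and mesenchymal genes, 18 of 30 fell and 4 rose, or 18 and 5 adjusted over the list alone (median log2 fold change -0.38, adjusted p = 1.59e-05, adjusted p = 0.0883 with an estimated correlation). FN1 was at -1.49 and COL6A3 at -1.51. For 46 NF-kB targets, 22 fell and 10 rose, the same numbers adjusted over the list alone (median log2 fold change -0.29, adjusted p = 0.0381, adjusted p = 0.230 with an estimated correlation). LIF was at -1.06 and NFKBIA at -0.53, against CCL2 (1.43) and VCAM1 (1.69), and the median was the same with a member at 0 set to its bound. Ribosomal protein genes fell, as 21 of 48 fell and 0 rose, or 26 and 0 adjusted over the list alone (median log2 fold change -0.16, adjusted p = 1.59e-05, adjusted p = 0.513 with an estimated correlation). Of 24 lists 14 passed, and 0 with an estimated correlation.

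The deposited comparison tables of the authors, turned to the sign of inhibitor over DMSO, called 5208 genes in wild-type cells (2364 higher and 2844 lower) and 3948 in knockout cells (1717 higher and 2231 lower) at the same threshold. Their log2 fold changes correlated with the edgeR values across genes at r = 0.997 over 18355 genes and r = 0.996 over 18262 genes, on the same counts, and 5101 and 3944 genes were called by both.

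**Figure D4:**
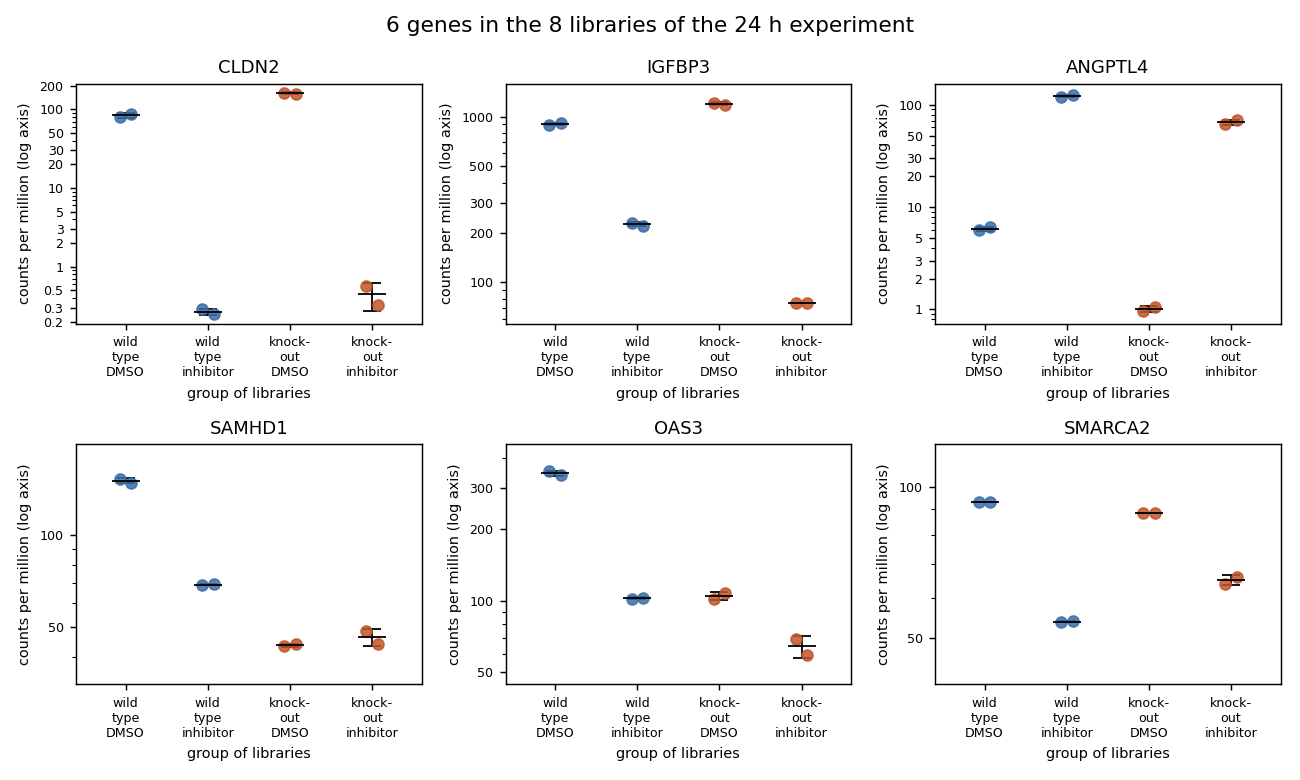
CPM on a log axis for selected genes in the 4 groups at 24 h, a point per library with the mean ± SD, wild type in blue and knockout in orange. IGFBP3 in the knockout fell from 1195 ± 28.4 to 75.2 ± 0.0220 CPM, and ANGPTL4 in wild type rose from 6.12 ± 0.306 to 122 ± 2.63 CPM.

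Whether the inhibitor acts differently without PBRM1 was tested as the difference of the responses. IGFBP3 fell more in the knockout (log2 difference -1.98, SE 0.0838, adjusted p = 2.46e-09). ANGPTL4 had a larger log2 rise there (log2 difference 1.75, SE 0.174, adjusted p = 8.43e-05). It started from a lower DMSO level, 0.965 and 1.05 CPM in the knockout libraries against 5.91 and 6.34 CPM in wild type. Its level under the inhibitor was lower too, at 64.7 and 70.4 against 120 and 124 CPM. SAMHD1, an antiviral nucleotide hydrolase gene, was at 69.0 ± 0.484 against 151 ± 2.84 CPM in wild type and at 46.3 ± 3.03 against 43.7 ± 0.515 CPM in the knockout (log2 difference 1.20, SE 0.0929, adjusted p = 6.08e-06). OAS3 (1.03), HELZ2 (1.08) and ANXA4 (0.91) also had a more positive response in the knockout, and ZNF736 (-1.20) a more negative response. OAS3 in knockout DMSO libraries (102 and 108 CPM) already lay near its level in inhibitor-treated wild-type libraries (102 and 103 CPM). In total 226 of 18373 genes differed, 127 more positive and 99 more negative, and 56 at least 2-fold (33 more positive and 23 more negative). Of 31 interferon-stimulated genes, 13 were higher and 0 were lower, or 20 and 2 adjusted over the list alone (median log2 difference 0.56, adjusted p = 1.50e-29, adjusted p = 0.0655 with an estimated correlation). PARP9 was at 1.14 and IFIH1 at 0.98. For NF-kB targets, 6 of 46 were lower and 3 were higher, or 13 and 6 adjusted over the list alone (median log2 difference -0.18, adjusted p = 0.00422, adjusted p = 0.163 with an estimated correlation). TRAF1 was at -0.71 against VCAM1 (0.57) and IL6 (1.34). BIRC3 was at -0.38 and NFKBIA at -0.37. These calls other than TRAF1 were not stable. BIRC3 (-0.34 to -0.43) and NFKBIA (-0.35 to -0.40) did not pass without any 1 of 6 libraries, the 2 of each wild-type group and the 2 with knockout DMSO. VCAM1 (0.55 to 0.60) did not pass without wild-type DMSO library 1 or either library of wild-type inhibitor or knockout DMSO, and IL6 (1.11 to 1.5) without any library but knockout DMSO library 2. All 4 also did not pass in some of the other alternatives, such as thinning to the smallest total. For matrix and mesenchymal genes, 3 of 30 were higher and 0 were lower, or 3 and 1 adjusted over the list alone (median log2 difference 0.138, adjusted p = 0.00629, adjusted p = 0.163 with an estimated correlation). Of 24 lists 6 passed, and 0 with an estimated correlation. The count depended on single libraries, at 372 without knockout inhibitor library 1, 366 without library 2 and 99 to 131 without any other library.

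Under DMSO in the 24 h experiment, knockout cells had less expression of interferon-stimulated genes than wild-type cells. RSAD2, the antiviral viperin gene, was at 0.351 ± 0.186 against 76.6 ± 6.28 CPM (log2 fold change -7.72, SE 0.202, adjusted p = 1.58e-13, n = 2 each). OAS1 (-6.18), IFI6 (-3.08) and IFIT1 (-2.57) were lower as well. VCAM1 was at 5.87 ± 0.111 against 59.6 ± 1.54 CPM (log2 fold change -3.34, SE 0.0805, adjusted p = 6.50e-14) and CCL2 higher at 54.4 ± 4.40 against 28.03 ± 0.410 CPM (log2 fold change 0.96, SE 0.0745, adjusted p = 6.89e-08). STC1 was at least 95.7-fold lower and MSX2 at least 64.1-fold lower against 0 counts in the knockout. Altogether 5513 of 18373 genes differed, 2545 higher and 2968 lower, and 1287 by at least 2-fold (379 higher and 908 lower).

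Of 31 interferon-stimulated genes, 30 were lower and 0 were higher, the same numbers adjusted over the list alone (median log2 fold change -1.84, adjusted p = 6.54e-36). The list also passed with an estimated correlation (adjusted p = 0.0452). NF-kB targets did not pass, as 18 of 46 were higher and 15 were lower, or 19 and 15 adjusted over the list alone (median log2 fold change 0.08, mean -0.52, test upward, not all of 1 sign, adjusted p = 0.771), with CXCL1 (-3.21) and IL6 (-2.05) lower and RELB (0.56) higher, while NFKBIA (0.142, adjusted p = 0.0735) and BIRC3 (0.12, adjusted p = 0.111) did not pass. C4BPB was higher (21.1 ± 0.113 against 1.21 ± 0.231 CPM, log2 fold change 4.11, SE 0.189, adjusted p = 1.00e-10). CYB5A had 1 count in wild-type libraries, a knockout over wild-type ratio of 548 with a counting interval of 98.0 to 21693. Of 30 matrix and mesenchymal genes, 15 were lower and 2 were higher, or 16 and 3 adjusted over the list alone (median log2 fold change -0.19, adjusted p = 0.00124, adjusted p = 0.115 with an estimated correlation). COL6A3 was at -2.49. Of p53 targets, 13 of 23 were lower and 2 were higher, the same numbers adjusted over the list alone (median log2 fold change -0.32, adjusted p = 0.00124, adjusted p = 0.115 with an estimated correlation). CDKN1A was at -1.51. Of 25 hypoxia and HIF targets, 15 were lower and 5 were higher, the same numbers adjusted over the list alone (median log2 fold change -0.45, adjusted p = 0.00178, adjusted p = 0.357 with an estimated correlation). ANGPTL4 was at -2.60 and CCND1 at -1.06, against HK2 (1.03). Proteasome subunits were higher more often, as 14 of 33 were higher and 2 were lower, or 17 and 2 adjusted over the list alone (median log2 fold change 0.136, adjusted p = 0.000844, adjusted p = 0.716 with an estimated correlation). Of 24 lists 7 passed, and 1 with an estimated correlation.

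**Figure D5:**
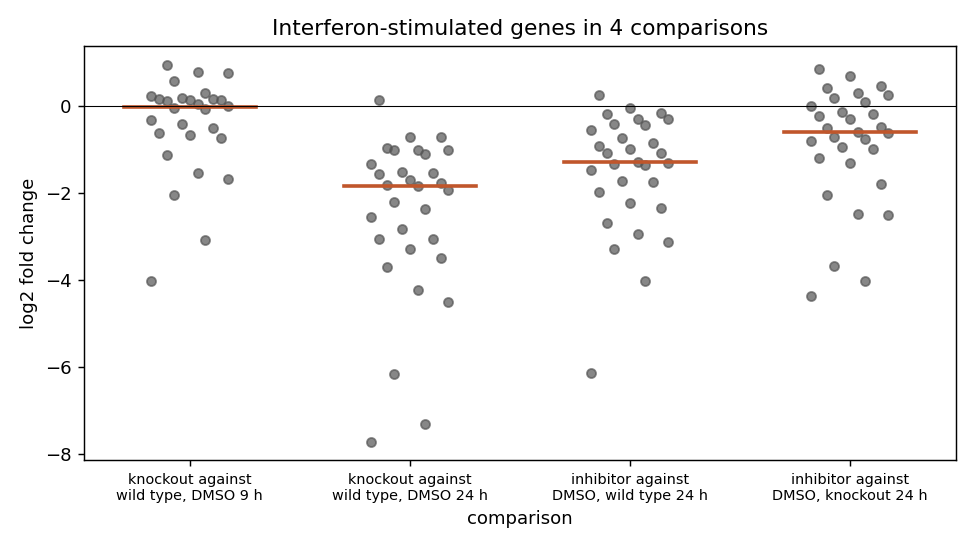
Log2 fold change on the vertical axis for interferon-stimulated genes in the comparisons on the horizontal axis, a point per gene and an orange line at the list median. Knockout over wild type under DMSO is shown at 9 h (28 genes) and 24 h (31 genes). Inhibitor over DMSO at 24 h is shown for wild-type and knockout cells (31 genes each). The median of knockout over wild type was -0.03 at 9 h and -1.84 at 24 h.

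Knockout effects under DMSO were compared between the experiments, which share no libraries and come in separate tables, so that time cannot be separated from other differences between them. Over 16477 genes the log2 fold changes correlated at r = 0.545 (rho = 0.313), and 2555 of 3161 genes called in both (80.8%) had the same sign, among them CDKN1A, COL6A3, C4BPB and CCL2. A model of all 20 libraries found 4795 of 16761 genes whose knockout effect differed, 2406 more positive and 2389 more negative at 24 h. For interferon-stimulated genes, 28 of 28 measured in both were more negative at 24 h (median log2 difference -1.78, adjusted p = 7.12e-38). At 9 h RSAD2 (-4.04), OAS1 (-3.09), OASL (-1.70) and IFI44L (-1.55) were lower in the knockout as well.

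Genes higher in the knockout at 9 h were compared with those lowered by the inhibitor in the knockout at 24 h, to ask whether expression gained without PBRM1 needs SWI/SNF ATPase activity. CLDN2 was higher in the knockout and lowered by the inhibitor, as were C4BPB (4.14 and -3.06), SPINT1 (3.42 and -2.46), KRT79 (2.31 and -4.47) and IRF8. The inhibitor lowered CLDN2 in wild-type cells too, from 80.0 and 88.1 to 0.284 and 0.250 CPM, and IRF8 at least 12.8-fold. Wild-type responses of C4BPB, SPINT1 and KRT79 are not given here. An overlap with genes lowered in wild type was not tested, nor whether a higher level in the knockout makes a fall easier to call. Of 16477 genes tested in both, 3736 were higher in the knockout, 3216 were lowered by the inhibitor, and 1204 were in both groups where 729 would be if they were independent (Fisher's exact test, two-sided, odds ratio 2.54, 95% interval 2.33 to 2.76, p = 4.27e-101). In reverse, 716 genes were lower in the knockout and raised by the inhibitor against 570 if independent (odds ratio 1.44), including SYT11 (-1.85 and 4.03), CLIP2 (-2.84 and 1.77) and ULBP1 (-2.40 and 2.20). Changes in the same direction gave odds ratios of 1.15 for 715 genes higher and raised (1.08 without knockout inhibitor library 2) and 1.38 for 771 genes lower and lowered. Genes are not independent, so these p-values overstate the certainty.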

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

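Of the tests in this part, those of the gene order along chromosomes, of chromosome 9 under bortezomib, of single libraries on the shifted chromosomes, of PBRM1 loss as a cause in both experiments and of a common scaling of the bortezomib response were chosen only after the result was seen.

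Several results stood out because an effect differed between groups by a test of the difference itself. The bortezomib response differed between knockout and wild type for 4327 genes. Among these were BIRC3 (-1.49), CCL2 (-1.96), CCND1 (-1.38) and EDN2 (-2.28), with a more negative log2 response in the knockout, and DDIT4 (1.95), SESN2 (2.17) and STC2 (1.71), with a more positive log2 response. The lists that differed in bortezomib response with both the preset and the estimated correlation, 7 of the 14 that passed with the preset, were NF-kB targets (median log2 difference -0.57), proteasome subunits (0.0763), the ubiquitin and p97 pathway (0.0982), heat shock (0.45), the integrated stress response (0.84), mitosis (-0.21) and DNA replication (-0.33). The ATPase inhibitor response differed for 226 genes, among them ANGPTL4 (1.75), ANXA4 (0.91), HELZ2 (1.08), IGFBP3 (-1.98), OAS3 (1.03), SAMHD1 (1.20) and ZNF736 (-1.20) as log2 differences. The knockout effect under DMSO differed between the 24 h and 9 h experiments for 4795 genes and for interferon-stimulated genes as a list (median log2 difference -1.78).

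The count of genes past the threshold was compared with other splits of the same libraries, which make 10 splits for 3 against 3 libraries, too few for a share under 0.05. The real split and the highest of the others gave 3902 and 1 genes for bortezomib in wild type, 8153 and 0 in the knockout, 7019 and 0 for the knockout under DMSO, and 8129 and 0 under bortezomib, so that 1 of 10 splits reached the real value in each. For lists the real split and the highest other gave 18 and 14, 15 and 15, 14 and 7, and 12 and 9. The real value was reached by 1, 2, 1 and 1 splits. Every other split mixes the groups unevenly and keeps part of the real difference, so these list counts are no reference for chance. For the difference of the bortezomib responses, 8 of 100 drawn splits gave at least the real 4327 genes, the highest being 8172. This count cannot decide on chance, because splits that keep the knockout labels leave the knockout bortezomib response in the contrast. The 7 other splits among these 8 all kept the knockout libraries in their labelled groups. Of these, 6 mixed the wild-type libraries and 1, with the highest count, mixed none and exchanged the wild-type bortezomib and DMSO labels. No split that mixed the knockout libraries gave more than 0 genes, so these counts hold no reference for chance. For lists 29 of 100 splits gave the real 14 or more, the highest being 18. Mixed splits keep part of the real differences here too, so this count cannot decide on chance either.

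The first pattern weighed was the larger bortezomib response in the knockout. After thinning to the smallest total count the knockout count was 2.20 times the wild-type count, which argues against a difference in total counts. With each library left out in turn the ratio was at least 1.91, which argues against an outlying library. The median fall of NF-kB targets was 3.10 times as large in the knockout and the median rise of proteasome subunits 1.246 times. The ratio of these was 2.49 (interval 1.77 to 3.25), which argues against a single multiplier of the log2 changes shared by both lists. The interval treats genes as independent. Among other lists, the knockout over wild-type ratio of medians was 3.13 for heat shock and 3.47 for the integrated stress response. For NRF2 targets it was 0.996 and for autophagy 1.02, so the larger response was not seen in every list. A common cause acting unequally on the lists was not tested. A biological dependence on genotype may remain as a hypothesis, but a difference between the clones other than PBRM1 was not tested and stays open.

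The next pattern was the lower expression of interferon-stimulated genes in the knockout at 24 h, with a list median of -1.84. With each DMSO library left out the median was -1.79 at the highest, which argues against a single library, and after chromosome medians were subtracted it was -1.93, which argues against chromosome-wide shifts. At 9 h the median was -0.0344 (interval -0.52 to 0.14), so PBRM1 loss alone as a cause acting alike on the list in both experiments is excluded. Single members such as RSAD2 (-4.04) and OAS1 (-3.09) were lower at 9 h too. A difference of the cells or cultures between experiments may be the source, and the design cannot separate it from time, since each experiment has its own libraries. Interferon signalling that was active in the wild-type cells at 24 h is a biological hypothesis that was not tested.

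The last pattern was a shift of chromosomes, or of parts of them, between knockout and wild type. On chromosome 9 the median log2 fold change was -0.25 under DMSO at 9 h and -0.27 under bortezomib (-0.268, interval -0.299 to -0.232), and -0.04 (-0.0386) at 24 h, while at 24 h the median was 0.27 on chromosome 22 and 0.26 on chromosome 13. In windows of mostly 50 genes, chromosome 9 under DMSO at 9 h was at -0.0101 and 0.0233 up to 37.8 Mb and at -0.217 to -0.357 beyond. Chromosome 10 was lower up to 42.4 Mb in both experiments (-0.264 and -0.247 at 9 h, -0.335 and -0.424 at 24 h), and the first window of chromosome 15 was at 0.438 at 24 h. None of 1000 shuffles of the gene order (0) gave a chromosome median as large, so chance order is excluded, and the bortezomib value argues against a bias of the DMSO libraries alone. The 24 h value of chromosome 9 argues against PBRM1 loss acting alike on this chromosome in both experiments. An effect of PBRM1 loss that differs between the experiments stays open. Medians under DMSO kept their sign on chromosome 12 (-0.1397 at 9 h and -0.0994 at 24 h) and chromosome 20 (0.1005 and 0.125). They changed sign on chromosome 7 (-0.103 at 9 h and 0.164 at 24 h) and chromosome 16 (0.177 and -0.106). PBRM1 loss as a cause was not tested for these chromosomes or for chromosome 10. Chromosome medians computed from separate libraries of an experiment correlated at Spearman's rho 0.714 (interval 0.571 to 0.825) or more, and the interval is not wholly above the value set in advance for excluding a bias of single libraries over all chromosomes, most of them not shifted. For the 10 DMSO medians beyond 0.1 in size, on 5 chromosomes per experiment, the treated libraries kept the sign and at least 0.704 of the DMSO median (interval 0.516 to 0.795), which argues against a bias of single libraries there. Copy-number differences between the cells sequenced may explain the shifts, a hypothesis that needs DNA data.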

How the results depend on the processing

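Of the alternatives in this part, thinning to the smallest total, leaving out ribosomal RNA genes or the libraries rich in them, subtracting chromosome medians, the joint model, and leaving out libraries for the list tests, overlap and correlation were chosen after seeing the data. In simulations with the counts and group sizes of these libraries, 32.6% of genes with a difference of 0.5 on the log2 scale were recovered for the difference of inhibitor responses and 58.7% to 65.2% for the other 24 h contrasts. The pseudocount and the thresholds in the authors' tables were planned for files without counts and were not run because the tables hold counts. The fit of the compared groups alone was not run for the differences of responses, where it is the same fit.

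Requiring a 2-fold change beside the adjusted p lowered every count by construction, to 98 for bortezomib in wild type, 715 in the knockout, 689 for the knockout at 9 h under DMSO, 874 under bortezomib, 275 for the difference of bortezomib responses, 1736 for the inhibitor in wild type, 1570 in the knockout, 1287 for the knockout at 24 h and 56 for the difference of inhibitor responses. The 8 contrasts other than the difference of inhibitor responses kept counts within 1.5 times the reported count under each scaling, filter, test, fit of fewer groups, replicate block and left-out library that was run. Which direction held more genes changed in some alternatives for 5 contrasts. For the knockout at 9 h under DMSO the 2-fold threshold gave 245 higher and 444 lower, against 3752 and 3267 reported. Under bortezomib it gave 263 higher and 611 lower, against 4095 and 4034. Upper-quartile factors gave 3432 higher and 3540 lower for the knockout at 9 h under DMSO, 3804 and 4274 under bortezomib, and 3328 upward and 3109 downward for the inhibitor in the knockout, each the reverse of the reported order. The knockout under bortezomib was also reversed with the 1 CPM filter (3928 and 3986) and without wild-type bortezomib library 1 (3696 and 3836), the difference of bortezomib responses with DESeq2 (2008 and 1987), and the difference of inhibitor responses without knockout inhibitor library 1 (174 and 198). Residuals of same-numbered libraries correlated at -0.0326 to 0.0419 at 9 h, and those of other-numbered libraries at -0.0439 to 0.0390. At 24 h same-numbered libraries gave -0.125 to 0.0613. With 2 libraries per group the other-numbered values there are the same with the sign turned, so they are no reference. These correlations cannot decide whether cultures were paired, because they span all genes, including those with few counts. With the number as a block the counts at 9 h were 3845 for bortezomib in wild type and 8113 in the knockout. They were 6954 for the knockout under DMSO, 8083 under bortezomib and 4292 for the difference of responses. The difference of inhibitor responses gave 153.

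With each library left out in turn, the count was 3184 to 3409 for bortezomib in wild type, 7461 to 7628 in the knockout, 6335 to 6425 for the knockout at 9 h under DMSO, 7471 to 7659 under bortezomib, 3878 to 4169 for the difference of bortezomib responses, 5054 to 5301 for the inhibitor in wild type, 4771 to 5904 in the knockout, and 3679 to 4121 for the knockout at 24 h. The difference of inhibitor responses ranged from 99 to 372 against 226 with all libraries. It was 99 and 108 without wild-type inhibitor libraries 1 and 2, 105 and 107 without wild-type DMSO libraries 1 and 2, 112 and 131 without knockout DMSO libraries 1 and 2, and 372 and 366 without knockout inhibitor libraries 1 and 2. Each 24 h setting leaves a group with 1 library, which is assumed to vary like the others. Knockout inhibitor libraries were the least alike of all pairs within a group, with a chi-square per degree of freedom of 157 between their counts. In other pairs it was at most 33.1. Thinning to the smallest total gave 143, a drop that fewer counts explain by construction, and leaving out both libraries rich in ribosomal RNA gave 302 genes, of which 136 were more positive and 166 more negative. DESeq2 gave 225, RLE scaling 239 and limma-voom 202.

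Of 216 list tests 114 passed, 38 with an estimated correlation and 191 with the mixed fry test, which asks whether members change in either direction. The directional fry test gave 151, RLE scaling 117, the replicate block 114, and each library left out 111 to 123. The correlation of the bortezomib responses was 0.623 over genes with at least 1 CPM in 3 libraries and 0.667 over genes past the threshold in either contrast, which by construction leaves out genes with small or noisy changes, and 0.462 to 0.495 with each library left out. The odds ratio of the overlap was 2.49 to 2.74 with each library left out, 3.18 at an adjusted p of 0.01 and 16.1 for changes of at least 2-fold. For changes of at least 2-fold it was 3.55 for genes lower and raised, 5.10 for lower and lowered, and 1.85 for higher and raised, so that lower and lowered had the larger ratio of the lower genes, the reverse of the order with all called genes (1.38 against 1.44). At an adjusted p of 0.01 these ratios were 1.63, 1.57 and 1.31. The ratio for higher and raised was 1.08 to 1.28 with each library left out. Lower and lowered also had a larger ratio than lower and raised without some single libraries. These were wild-type DMSO library 2 at 9 h, knockout DMSO library 1 of either experiment, and knockout inhibitor library 1.

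Of 257 tests of single genes named in the texts, 245 were past the threshold, and of these 233 stayed past it in every alternative fit, 12 did not pass in some and 0 passed with the other sign. Of 12 not past the threshold, 5 passed in some. The genes lost with a library left out were, for the difference of inhibitor responses, BIRC3, NFKBIA, VCAM1, IL6 and GDF15, and otherwise MMP9 for bortezomib in wild type, IFI35 for the inhibitor in wild type, ARID2 for the inhibitor in the knockout, and MT1F and MT1X for the knockout at 9 h. Each is given with its libraries where it is named. Other alternatives also lost some of them. Thinning lost the 5 of the inhibitor difference, MMP9 and MT1X, and the replicate block BIRC3, NFKBIA, IL6 and GDF15. The fit with no filter lost NFKBIA and IFI35, limma-voom VCAM1, IL6 and GDF15, and DESeq2 IL6, IFI35 and MT1X. Leaving out both libraries rich in ribosomal RNA lost VCAM1, IL6, GDF15 and ARID2, and upper-quartile factors and the fit of the compared groups alone lost MT1X. Of genes kept in every other fit, DESeq2 did not call PIGZ for bortezomib in wild type (-1.21) or MT-ND5 for the difference of bortezomib responses (1.11). At 24 h under DMSO, fitting only the groups compared called BIRC3 (0.13) and NFKBIA (0.15), and limma-voom NFKBIA (0.142). For the difference of inhibitor responses, upper-quartile factors called SMARCA2 (0.37). The cause of these changes was not tested.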

Other observations

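Most measured genes typical of other cell types were at low levels, apart from fibroblast markers at 24 h. Among leukocyte markers CORO1A had means of 1.09 to 2.09 CPM in the 4 groups at 9 h and 0.916 to 1.82 CPM at 24 h. The endothelial markers TIE1, TEK and KDR were at 0.476 CPM or less in each group at 24 h and were not listed at 9 h. The highest group means of fibroblast markers at 24 h were 8.97 CPM for PDGFRB, 9.93 CPM for LUM and 10.4 CPM for COL14A1. PDGFRB fell under the ATPase inhibitor in wild-type cells (-3.69) and knockout cells (-4.20), and in knockout DMSO cells at 24 h COL14A1 was higher (2.57) and LUM lower (-1.68) than in wild type. The nephron segment marker CUBN was at 0.663 to 1.81 CPM at 9 h and fell under bortezomib in the knockout (-1.28).

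Metallothionein genes, whose reads the counts cannot assign with certainty among near-identical paralogs, had 4 measured members. Under DMSO at 9 h MT1E (-0.41), MT1F (-0.59) and MT2A (-0.40) were lower in the knockout and MT1X (0.26) was higher. MT1F did not pass without knockout DMSO library 2 (-0.53) or wild-type DMSO library 3 (-0.51), nor MT1X without knockout DMSO library 3 (0.16) or wild-type DMSO library 1 (0.23) or 2 (0.24), and MT1X was also lost in 4 other alternatives. Bortezomib lowered MT1E (-0.66) and MT1X (-0.39) in the knockout, and MT1E did not pass the threshold in wild-type cells (-0.10, adjusted p = 0.0834), though it did without wild-type DMSO library 2 (-0.16) or 3 (-0.13).

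Single genes of the lists also differed, such as the stress cytokine gene GDF15, lower in the knockout at 24 h (-4.43) and with a more positive inhibitor response there (1.38), and the mitochondrial gene MT-ND5, with a more positive bortezomib response in the knockout (1.09). The inhibitor call for GDF15 was lost (1.13 to 1.46) without any 1 library of the 24 h experiment but knockout inhibitor library 2, and in 4 other alternatives.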
